A study of Bacillus cereus ATCC 10987 with 12 samples.

How the data were processed

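Total RNA of the Bacillus cereus strain that carries plasmid pBc10987 was measured on 12 two-colour Agilent arrays of a custom design. Per the labels' protocols, 15 μg of total RNA was copied into cDNA and labelled with a post-labelling kit. The growth conditions compared were mid-logarithmic and stationary planktonic cells and biofilms grown for 12 or 24 h. Every pair of conditions was hybridised on 2 arrays with the dyes swapped. The labels name 8 RNA samples, 2 per condition. Sample 1 was always labelled Cy3 and sample 2 always Cy5, and each was on 3 arrays. The dye and the RNA sample number are therefore one factor. The design text speaks of duplicate experiments but names no separate cultures, so p-values measure only the spread between these RNA samples, which may be partly technical.

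The deposited scanner files give, per the file headers, spot intensity values from Agilent Feature Extraction 9.5.1.1. The mean signal and the local background median were used. They are intensity values on a linear scale with no normalization, per the file headers. A processed intensity is also deposited. It has a spatial background surface subtracted and is dye-normalized within the array, with a LOWESS smooth factor of 0.25 per the file headers. The background subtracted equalled the fitted surface in 100% of spots. The deposited files also hold 0 or 1 marks for outlier spots, saturation and signals well above background, set by the scanner software per the file headers. The authors' value table holds log2 values. Set against the scanner files, each of its 12 columns was log2 of the Cy5 over the Cy3 processed signal, with a largest difference of 4.9e-08, and no further centring. The column medians ran from −0.19 to 0.37. The genome build and annotation behind the probes are not given in the sources used here.

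Each array had 18777 spots, of which 1080 were controls and 17697 held 16215 distinct probes for genes. The files pair no tag with a gene name or product. Tags are therefore reported by identifier. Those of the form BCE plus a number are called chromosomal, those starting BCE_A are called plasmid tags, as fixed before the data were examined, and those starting sRNA keep that word. Of 5899 tags, 5578 were chromosomal, 240 were plasmid tags and 81 were sRNA tags.

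Background was corrected with normexp at an offset of 50 on all spots, and the channels of each array were then normalized by loess, with controls and outlier spots at weight 0. Controls and outlier spots were then left out, and saturated spots were kept. Spots of a probe were averaged. A probe was kept if it was well above background in at least 4 of the 6 channels of at least 1 condition, counting a probe with at least 50% of its spots above background as above. This left 13890 probes. Different probes of a tag were averaged with equal weight, giving 5480 tested tags, of which 5206 were chromosomal, 197 plasmid and 77 sRNA tags. One probe stood behind 804 tags, 2 probes behind 942 and 3 probes behind 3734. The other 419 tags were not tested. A probe sequence was shared by tags in 24 cases, which involved 30 tags, none of them named here.

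For each tag, least squares of the 12 log2 ratios gave 8 RNA sample levels, with a pooled SD of 0.353 log2 around them. These 8 values were fitted with limma lmFit and eBayes on condition plus RNA sample number, with 3 residual and 2.13 prior degrees of freedom and a prior SD of 0.219. The gene-specific dye term exceeded 1 log2 in size for 40 tags. The 8 contrasts were the 6 pairs of conditions, both biofilms against both planktonic phases, and the difference between the change from 12 to 24 h in biofilm and the change from mid-log to stationary phase. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested tags and a threshold of 0.05. R 4.3.3, limma 3.58.1 and the R package data.table, version 1.17.8, were used. Every fold is on the scale of background-corrected signal plus 50, which lowers the folds of dim tags. Against median centring, loess moved the log2 ratio of a spot by a median of 0.11 up to a mean log2 signal of 7 and by 2.42 above 13, so folds of bright tags can be too high or too low. They are therefore given beside folds under median centring and, for pairs of conditions, the ratio of the median channel signals after the exchange of channels. Those channel signals are mean scanner signals with no background subtracted and no normalization. They are averaged over all spots of a tag, outlier spots and filtered probes included, so these ratios and the fitted folds are unlike measures.

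Ratios give differences only, so an error that turned every array would turn every sign and, for the same tested tags, leave the p-values as they are. The filter on dim probes and the fit on separate channels depend on which channel belongs to which condition, and both were also run exchanged. Single-channel levels were therefore compared between arrays that carry the same RNA sample, with the channels as labelled and exchanged. For this comparison, normexp-corrected log2 signals were quantile-normalized over the arrays within each dye. Each spot's mean over the arrays was then subtracted within each dye. The fit on separate channels instead used levels after loess and Aquantile.

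Of 45 gene lists fixed before the data were examined, 44 need gene names or products and could not be matched. The plasmid list could. It was tested with limma camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 8 comparisons. As the files pair no tag with a name, only the 2 highest and 2 lowest tags of each comparison are named, from those past the threshold that changed the same way in RNA samples 1 and 2. The rule fixed before the data were examined asked for 6 at each end, 5 for the difference in change over time, without hypothetical products, and for list members and a fixed set of known genes. Those parts need names and were not applied. Added after the data were examined were a list of the sRNA tags, windows of 100 tag numbers, and the longest runs of consecutive tested tags called one way, with 1000 permutations of the tag order for the run length.

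The arrays came from 12 slides and 1 scan day, so no slide held more than 1 array, and neither slide nor scan day could be a block. Median signals were 99.0 to 237 in Cy3 and 76.9 to 162 in Cy5. From 74.3 to 92.1% of spots were well above background in Cy3 and 58.5 to 86.8% in Cy5. Outlier spots made up 0.0339 to 3.36%. From 1 to 85 spots were saturated in Cy3 and from 0 to 34 in Cy5. The number of RNA samples, 2 per condition, limits the precision.

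The fit was tested on simulated data for 24 h against 12 h biofilm, with 5480 tags of which 200 were changed. It recovered 0 of 67 tags changed 1.5-fold, 0 of 67 changed 2-fold and 38 of 66 changed 4-fold (57.6%), with 4 false calls. An unchanged comparison gave 0 calls. The simulated tags were independent, had the same spread in all conditions, and few of them were changed. In the data, 18.3% of tags were called in this comparison. The recovery at each fold is therefore not the power of the fit on the data.

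The alternatives fixed beforehand were the processed signals, no background subtraction, an offset of 10, median centring, scale normalization between arrays, separate channels, the authors' value table, no filter on dim probes, a filter asking for all 24 channels, the median or the brightest probe, the 12 arrays as independent units, a fit without the RNA sample number, outlier spots kept, an adjusted p threshold of 0.01, and leaving out each RNA sample or array in turn. Those added after the data were examined were detection and separate channels with the channels exchanged, conditions weighted by their spread, the 24 h biofilm arrays left out, and probes left out that stood apart in 1 RNA sample.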

Results

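Gene expression of the Bacillus cereus strain that carries plasmid pBc10987, a Gram-positive soil and food bacterium, was compared between free-swimming (planktonic) cells and biofilms, which are cell layers held in a matrix. The 12 arrays covered 4 conditions, mid-logarithmic and stationary planktonic cells and biofilms of 12 and 24 h. Each of the 6 pairs of conditions was on 2 arrays with the dyes swapped, and each condition was represented by 2 RNA samples. Of 5899 tags on the array, 5480 were tested, 5206 of them chromosomal, 197 on plasmid pBc10987 and 77 sRNA tags. Between 58.5 and 92.1% of spots were well above background in a channel.

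The signals went against the labelled direction of every comparison. With the dyes as labelled, the channels that should hold one RNA sample on different arrays correlated at a mean r of −0.32 across spots, from −0.73 to 0.03, with 23 of 24 pairs below 0. With the green and red channels exchanged, the same 24 pairs correlated at a mean of 0.93, from 0.77 to 0.99. The mean correlation of an array's channels with all channels of the same condition on other arrays was higher after the exchange on 12 of 12 arrays. Spots are not independent replicates, so no p-value is attached to these correlations. An exchange of the 2 arrays of every dye-swapped pair would look the same, apart from which RNA sample number a sample carries. For a given set of tested tags, the exchange turns the sign of every log2 ratio and leaves its size, SE and p-value as they are. It changed the filter on dim probes, which tested 5655 tags when exchanged, and the fit on separate channels. The correlations argue against the directions as labelled, though no record of the hybridisations was available. Values are still given as labelled with the filter as labelled. Each direction is also given with the channels exchanged, called exchanged from here on, which is the reading that the signals favour. For separate channels, exchanged values come from a fit of their own, in which all 32 named values kept their call.

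**Figure D1:**
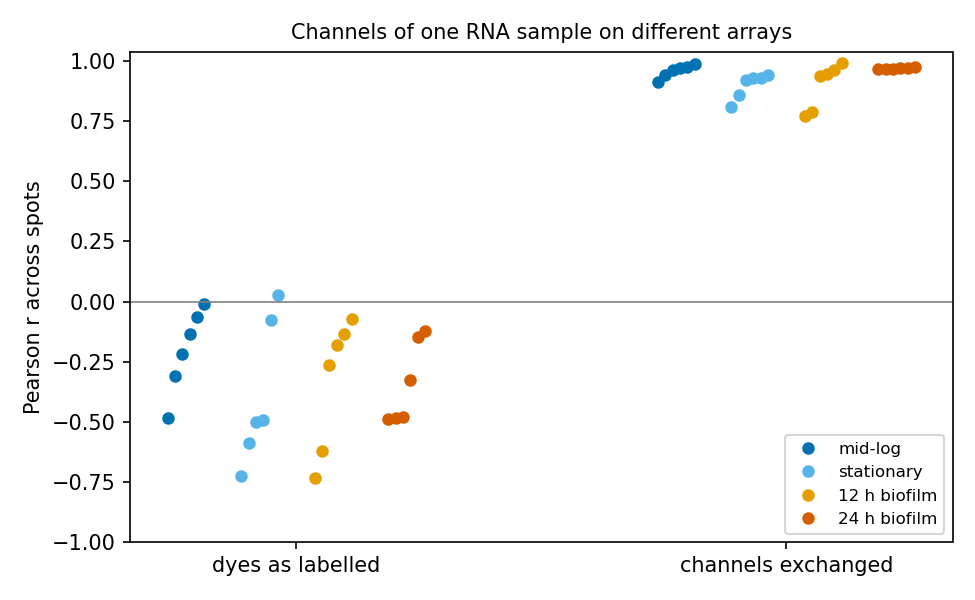
Pearson correlation across spots (y axis) of single-channel levels between 2 arrays that carry the same RNA sample, 6 pairs per condition, with the dyes as labelled (left) and with the channels exchanged (right). Labelled values lie between −0.73 and 0.03 and exchanged values between 0.77 and 0.99.

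The signals of single tags showed the same split. For BCE0165, the 6 mid-log channels read 23976 to 52727 scanner units after the exchange and the channels of the other 3 conditions at most 316. As labelled, its signals ran from 69 to 47602 within stationary cells and from 79 to 37805 within the 12 h biofilm. BCE5405 read 2543 to 12842 in the biofilm channels and at most 206 in the planktonic ones after the exchange, and from 55 to 12309 within the 12 h biofilm as labelled. Both tags are named below by rule, and were chosen for this display after their values were seen.

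**Figure D2:**
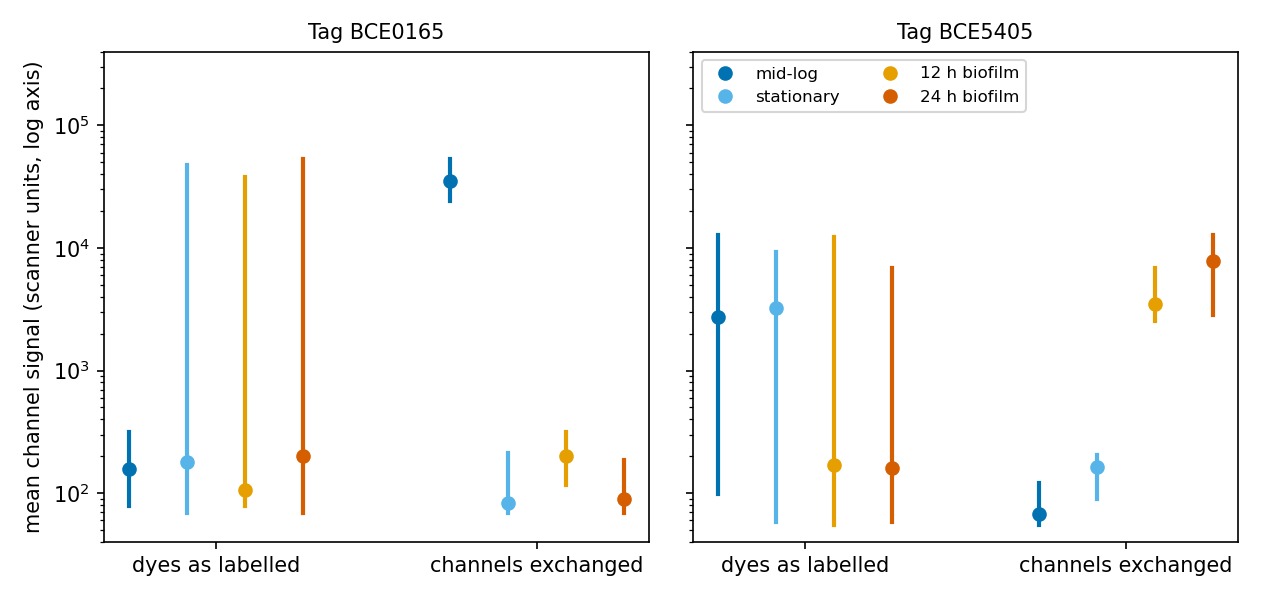
Mean channel signal in scanner units (log axis) of the tags BCE0165 and BCE5405 in each condition, as the median (point) and the range (bar) over 6 channels, with the dyes as labelled and with the channels exchanged. After the exchange, BCE0165 lies between 23976 and 52727 in mid-log cells and at most at 316 elsewhere.

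The conditions stood at unequal distances. The root mean square log2 difference over all tags was 1.83 between the 24 h biofilm and mid-log cells, 1.59 between the 12 h biofilm and mid-log cells and 1.33 between stationary and mid-log cells. It was 1.21 between the 2 biofilms, 1.20 between the 12 h biofilm and stationary cells and 1.14 between the 24 h biofilm and stationary cells. The lower distances had no fixed order, since the last one was 1.39 in RNA samples 1 and 1.08 in RNA samples 2, against 1.37 and 1.24 between the biofilms, 1.23 and 1.27 between the 12 h biofilm and stationary cells and 1.36 in both between stationary and mid-log cells. The 2 RNA samples of a condition correlated across tags at 0.93 in mid-log cells, 0.83 in stationary cells, 0.78 in the 12 h biofilm and 0.62 in the 24 h biofilm. Each tag's mean difference between samples 1 and 2 over the 4 conditions (its mean sample difference) was then subtracted. What was left was at least 2-fold for 155, 239, 237 and 595 tags, in that order, so the 24 h biofilm samples differed most from each other. In 24 h biofilm sample 1, 324 probes of 317 tags were at least 3 log2 lower as labelled and 8 probes higher (the reverse exchanged). In 311 of the 317 tags it was 1 probe only, so part of the 595 may come from single probes. The 595 were not counted again without those probes. Tags named below changed the same way in both RNA samples. Folds of named tags depended on the loess step, which moved the log2 ratio of bright spots by a median of 2.42. In 6 of the 24 named values of pairs of conditions, the fitted fold was above the ratio of the highest to the lowest channel signal after the exchange. It was over 1.5 times the ratio of median signals in 9 of the 24 and under it by more than 1.5 times in 7. As the signals are uncorrected and cover all spots of a tag, a fitted fold above their ratio is not thereby shown to be wrong. Folds are also not exact sizes where a condition was saturated in a channel or well above background in 3 or fewer of its 6 channels. After the exchange that held for conditions compared below in BCE0744, BCE1968, BCE2114, BCE2486, BCE4512 and BCE5405. BCE2216 and sRNA_BCE058 rest on 1 probe each, and for BCE1392, with 3 probes, 1 was measured on enough arrays for a fit of its own.

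**Figure D3:**
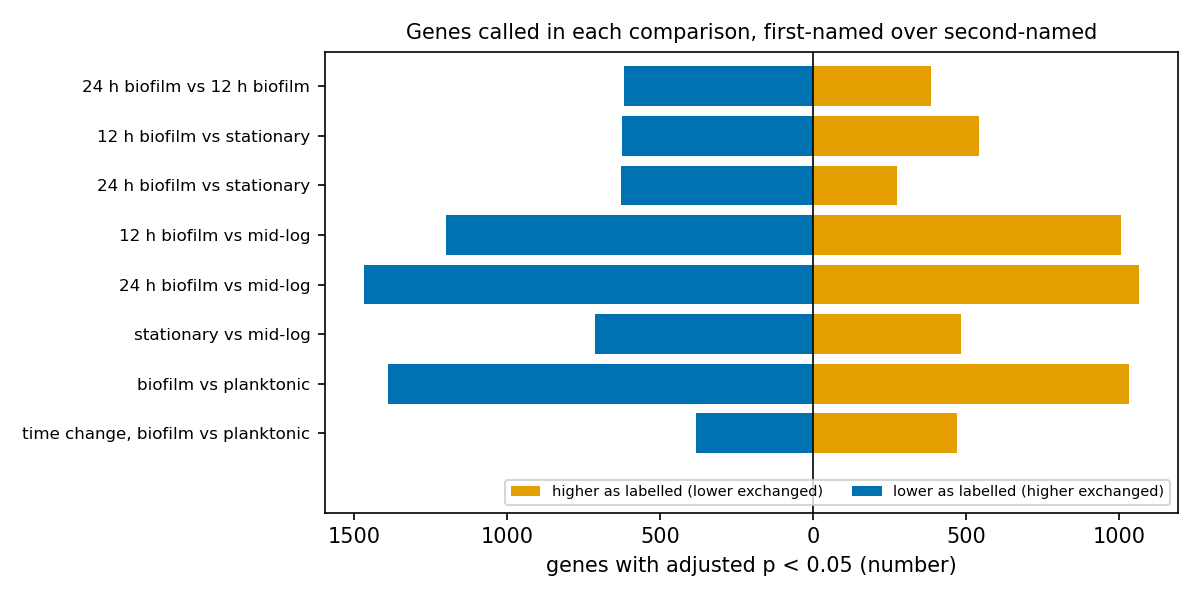
Number of tags with limma adjusted p under 0.05 (x axis) in each of the 8 comparisons, first-named condition over second-named. Bars to the right are tags higher as labelled and lower exchanged, and bars to the left the reverse. The numbers called run from 856 for the difference in change over time to 2534 for the 24 h biofilm against mid-log cells.

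Biofilm cells were set against planktonic cells, the comparison in the series title, as the mean of both biofilm ages against the mean of both planktonic phases. Of the 5480 tags, 2423 differed in limma's test. They split into 1032 higher and 1391 lower in biofilm as labelled, and 1391 higher and 1032 lower exchanged. At least 2-fold differences were 473 higher and 929 lower as labelled (929 and 473 exchanged). BCE5032 differed 22.7-fold (log2 4.50 ± 0.22 SE, n = 2 RNA samples per condition, adjusted p = 0.0011). BCE2037 differed 12.2-fold (log2 3.61 ± 0.50, adjusted p = 0.0049). Both were higher in biofilm as labelled and higher in planktonic cells exchanged. BCE5405 differed 77.4-fold (log2 −6.28 ± 0.56, adjusted p = 0.0019) and BCE4512 67.1-fold (log2 −6.07 ± 0.38, adjusted p = 0.0013). This pair was higher in planktonic cells as labelled and higher in biofilm exchanged. In mid-log cells after the exchange, BCE4512 was well above background in 2 of 6 channels and BCE5405 in 3 of 6, so neither fold is an exact size. Under median centring the 4 log2 values were 5.13, 4.49, −5.72 and −5.59 as labelled, in the order given, and −5.13, −4.49, 5.72 and 5.59 exchanged.

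Long runs of neighbouring tag numbers moved together between biofilm and planktonic cells. The 41 tested tags from number 104 to 144 were all called, with a median log2 of 2.28 (median SE 0.27), higher in biofilm as labelled and in planktonic cells exchanged. Within growth modes, 0 of these 41 tags were called between the 2 biofilms and 1 between stationary and mid-log cells. The 15 tested tags from 1323 to 1338 were called the other way, with a median log2 of −2.58, lower in biofilm as labelled and higher exchanged. Both runs were longer than any in 1000 permutations of the tag order, where the longest were 8 and 12 tags (permutation p = 0.001, the smallest they can give). Log2 values of neighbouring tags correlated at 0.378 to 0.488 over the 8 comparisons, and permuting the order removes this likeness. Here and below, the permutation p therefore shows only that called tags lie together, not that a run is unusual among such neighbours. Runs of different comparisons partly cover the same tags. The runs were looked for after the data were examined, and sizes depended on the scaling. The median of tags 104 to 144 was 3.76 under median centring (−3.76 exchanged), and that of tags 1323 to 1338 was −4.89 with processed signals and −3.89 at an offset of 10 (4.89 and 3.89 exchanged). Of the 16 run medians over the 8 comparisons, 8 moved by over 1.5 times with processed signals, 2 under median centring and 1 at an offset of 10.

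**Figure D4:**
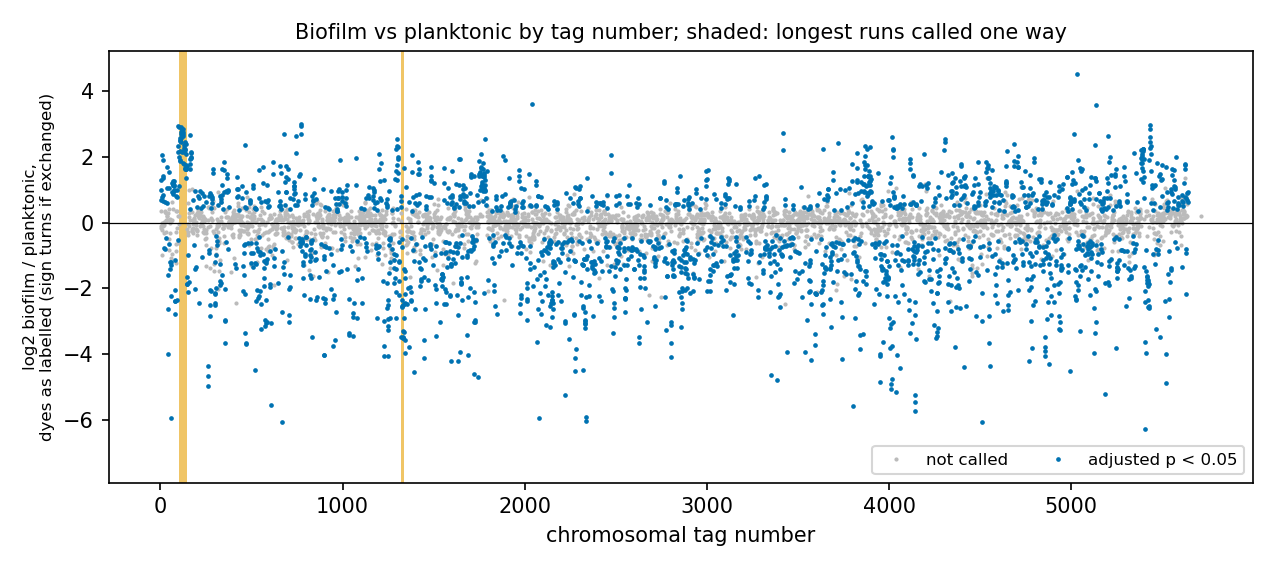
Log2 ratio of biofilm over planktonic cells as labelled (y axis, signs turn when exchanged) against the number in the chromosomal tag (x axis), with tags past adjusted p 0.05 in blue, others in grey and the longest runs called one way shaded. The 41 tags from 104 to 144 have a median of 2.28 as labelled (−2.28 exchanged), and the 15 tags from 1323 to 1338 a median of −2.58 (2.58 exchanged).

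The tags of plasmid pBc10987 were tested as a list between biofilm and planktonic cells. As labelled, 67 of its 197 tested tags were higher in biofilm, 22 lower and 108 not called, and 68 and 22 when adjusted over the list alone. Exchanged, 22 were higher and 67 lower. The list's median log2 was 0.29 as labelled (−0.29 exchanged) against −0.05 for the other tags (0.05 exchanged), and 0.96 with processed signals and 0.55 at an offset of 10 (−0.96 and −0.55 exchanged). The camera adjusted p was 2.18e-05 at the preset correlation, against an adjusted p of 0.503 with an estimated correlation of 0.128. None of the list calls in the 8 comparisons held with the estimated correlation.

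The count of 2423 fell to 1083 without stationary sample 1, 1085 without stationary sample 2, 1550 without mid-log sample 1, 1567 without 12 h biofilm sample 2 and 1613 without mid-log sample 2. Other settings gave 1204 to 3964 tags, the majority turned to 1664 higher and 1597 lower as labelled with processed signals and 1674 and 1603 in the authors' values (1597 and 1664, and 1603 and 1674 exchanged), and separate channels gave 203 and 1135 as labelled and 1479 and 1288 exchanged, while the 4 named tags stayed past the threshold in each setting that measured them.

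The 12 h biofilm was compared with mid-log cells, and 2209 tags differed, 1008 higher and 1201 lower in biofilm as labelled (1201 and 1008 exchanged). The majority turned without mid-log sample 2. At least 2-fold differences made up 704 higher and 1003 lower as labelled (1003 and 704 exchanged). BCE0165 (44.5-fold, log2 5.48 ± 0.56, adjusted p = 0.0027) and BCE1780 (40.2-fold, log2 5.33 ± 0.40, adjusted p = 0.0019) were higher in the biofilm as labelled and in mid-log cells exchanged. BCE1392 (fitted fold 1300, log2 −10.35 ± 1.32, adjusted p = 0.0043) and BCE0667 (614-fold, log2 −9.26 ± 0.68, adjusted p = 0.0019) were higher in mid-log cells as labelled and in the biofilm exchanged. For these 4 tags in order, the folds were 195, 115, 254 and 269 under median centring, and the median signals after the exchange differed 176-, 175-, 304- and 358-fold. For BCE1392, the fitted fold was thus above any ratio of its signals, at most 519. The 16 tested tags from 1745 to 1764 were called higher in the biofilm as labelled and lower exchanged, with a median log2 of 2.74, and 5.67 with processed signals (−2.74 and −5.67 exchanged). The 20 from 1513 to 1533 were called lower as labelled and higher exchanged, at −2.37, and −4.13 with processed signals (2.37 and 4.13 exchanged; permutation p = 0.001 for each run). On the plasmid, 78 tags were higher as labelled and 17 lower (17 and 78 exchanged), or 79 and 20 adjusted over the list alone. The camera adjusted p was 9.85e-07, and the adjusted p 0.503 with the estimated correlation. Counts were 1066 without mid-log sample 1, 1116 without 12 h biofilm sample 2, 1154 without mid-log sample 2, 1290 without 12 h biofilm sample 1, 1366 without stationary sample 2 and 1395 without stationary sample 1, and BCE1392 was not called without mid-log sample 2 (adjusted p = 0.0532). Other settings gave 878 to 3689 tags, and separate channels gave 99 higher and 779 lower as labelled, without BCE0165 (adjusted p = 0.191) and BCE0667 (adjusted p = 0.226), and 1357 and 1241 exchanged, with both.

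The 24 h biofilm differed from mid-log cells in 2534 tags, the highest number of the 8 comparisons, with 1065 higher and 1469 lower as labelled (1469 and 1065 exchanged). Of these, 730 higher and 1230 lower as labelled (1230 and 730 exchanged) differed at least 2-fold. The highest rank was lost with weights by condition, at 2278 tags against 2552 for the 12 h biofilm against mid-log cells and 2413 for biofilm against planktonic cells. It was also lost without any of 24 h biofilm samples 1 and 2 and mid-log samples 1 and 2. BCE2486 had a fitted fold of 1410 (log2 −10.46 ± 0.72, adjusted p = 0.00079) and BCE2114 of 1100 (log2 −10.11 ± 0.65, adjusted p = 0.00072), higher in mid-log cells as labelled and in the biofilm exchanged. After the exchange, BCE2486 was saturated in 2 of the 6 channels of the 24 h biofilm and BCE2114 in 1, and BCE2114 was well above background in 3 of 6 mid-log channels, so neither fold is an exact size. BCE0165 (52.1-fold, log2 5.70 ± 0.56, adjusted p = 0.0018) and BCE0744 (39.3-fold, log2 5.30 ± 0.49, adjusted p = 0.0015) were higher in the biofilm as labelled and in mid-log cells exchanged. After the exchange, BCE0744 was well above background in 2 of 6 channels of the biofilm, so its fold is not an exact size. In the order of naming, the folds of the 4 tags were 576, 534, 263 and 119 under median centring, and the median signals after the exchange differed 666-, 600-, 390- and 179-fold, at most 1170-fold for BCE2486. Less each tag's mean sample difference, the 2 RNA samples of the 24 h biofilm were at least 2-fold apart for 595 tags. The 15 tested tags from 127 to 141 had a median log2 of 2.35, which was 5.15 under median centring and 3.92 with processed signals (−2.35, −5.15 and −3.92 exchanged). The 13 from 2327 to 2340 had a median of −2.95 (2.95 exchanged). Each run was called one way throughout (permutation p = 0.001). On the plasmid, 66 tags were higher as labelled and 30 lower (30 and 66 exchanged), also when adjusted over the list alone. Its camera adjusted p was 0.000608, against an adjusted p of 0.503 with the estimated correlation. The count was 1361 without mid-log sample 2 and 1444 without mid-log sample 1. Across other settings it ran from 1363 to 4200, median centring gave 1470 higher and 1144 lower as labelled, processed signals 1777 and 1678 and the authors' values 1781 and 1695 (1144 and 1470, 1678 and 1777, and 1695 and 1781 exchanged), and separate channels gave 176 and 1529 as labelled, without BCE0165 (adjusted p = 0.311), and 1512 and 1335 exchanged, with it.

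Between stationary and mid-log cells, the change within planktonic growth, 1198 tags differed, 484 higher and 714 lower in stationary cells as labelled (714 and 484 exchanged). The majority turned without mid-log sample 2 and under median centring. At least 2-fold differences made up 321 higher and 624 lower as labelled (624 and 321 exchanged). BCE2486 had a fitted fold of 1800 (log2 −10.81 ± 0.72, adjusted p = 0.0022) and sRNA_BCE058 of 934 (log2 −9.87 ± 0.52, adjusted p = 0.0019), both higher in mid-log cells as labelled and in stationary cells exchanged. BCE0165 (57.3-fold, log2 5.84 ± 0.56, adjusted p = 0.004) and BCE1968 (50.6-fold, log2 5.66 ± 0.34, adjusted p = 0.002) were higher in stationary cells as labelled and in mid-log cells exchanged. BCE1968 was well above background in 1 of 6 stationary channels after the exchange, so its fold is not an exact size. In the order of naming, the 4 folds were 419, 164, 260 and 177 under median centring, and the median signals after the exchange differed 584-, 146-, 423- and 206-fold. The fitted folds of the first 2 tags were above any ratio of their signals, at most 1140 and 457, and sRNA_BCE058 had values on 11 of 12 arrays. The 12 tested tags from 1766 to 1777 had a median log2 of 2.75, and 4.80 with processed signals (−2.75 and −4.80 exchanged). The 21 from 1513 to 1534 had one of −2.97, and −5.15 with processed signals (2.97 and 5.15 exchanged). Each was called one way throughout (permutation p = 0.001). On the plasmid, 51 tags were higher as labelled and 11 lower (11 and 51 exchanged), or 57 and 16 adjusted over the list alone. The list had a camera adjusted p of 0.000252, and an adjusted p of 0.503 with the estimated correlation. Without stationary sample 1 limma called 2 tags, with 1201 at an unadjusted p under 0.05 and none of the 4 named ones among them (adjusted p = 0.0524 to 0.122), and the count was 168 without mid-log sample 2, 186 without stationary sample 2 and 377 without mid-log sample 1. BCE2486 (adjusted p = 0.0541) and sRNA_BCE058 (adjusted p = 0.0528) were not called without mid-log sample 2, nor BCE0165 without stationary sample 2 (adjusted p = 0.0639) or with separate channels as labelled (adjusted p = 0.381, called exchanged), and other settings gave 364 to 3266 tags, with 1041 higher and 512 lower as labelled under median centring (512 and 1041 exchanged) and 39 and 652 with separate channels as labelled, but 849 and 784 exchanged.

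The 12 h biofilm and stationary cells differed in 1167 tags, 543 higher and 624 lower in the biofilm as labelled (624 and 543 exchanged). At least 2-fold differences made up 384 higher and 536 lower as labelled (536 and 384 exchanged). BCE2346 (259-fold, log2 8.02 ± 0.19, adjusted p = 0.00059) and BCE2216 (149-fold, log2 7.22 ± 0.64, adjusted p = 0.0045) were higher in the biofilm as labelled and in stationary cells exchanged. BCE0667 (203-fold, log2 −7.67 ± 0.68, adjusted p = 0.0045) and BCE2078 (121-fold, log2 −6.92 ± 0.47, adjusted p = 0.003) were higher in stationary cells as labelled and in the biofilm exchanged. The 4 folds were 232, 88.6, 137 and 78.2 under median centring, and the median signals after the exchange differed 192-, 46.6-, 238- and 137-fold. For BCE2216 the fitted fold was above any ratio of its signals, at most 115, and BCE2346 and BCE0667 had values on 9 and 11 of 12 arrays. The longest runs were the 13 tested tags from 113 to 125, with a median log2 of 2.95 (−2.95 exchanged), and the 11 from 5415 to 5425, with −1.49 (1.49 exchanged; permutation p = 0.001 each). On the plasmid, 22 tags were higher as labelled and 8 lower (8 and 22 exchanged), or 9 and 5 adjusted over the list alone. The list's camera adjusted p was 0.00375, against an adjusted p of 0.514 with the estimated correlation and 0.181 with separate channels as labelled (0.00361 exchanged). Without stationary sample 1 limma called 2 tags (1219 at an unadjusted p under 0.05), without BCE2216, BCE0667 and BCE2078 (adjusted p = 0.0848 to 0.102), and the count was 192 without stationary sample 2, where BCE2216 and BCE0667 were not called (adjusted p = 0.0691 and 0.0563), 260 without 12 h biofilm sample 2, 466 without 12 h biofilm sample 1, 595 without mid-log sample 1 and 686 without mid-log sample 2. Other settings gave 306 to 3420 tags, median centring 317 higher and 729 lower as labelled, processed signals 1166 and 1033, the authors' values 1204 and 1045 (729 and 317, 1033 and 1166, and 1045 and 1204 exchanged), and separate channels 246 and 337 as labelled, without BCE0667 (adjusted p = 0.132), and 783 and 799 exchanged, with it. The majority also turned with the 12 arrays as units, at 1832 higher and 1588 lower as labelled (1588 and 1832 exchanged). With the filter asking for all 24 channels it turned narrowly, at 300 and 297 as labelled (297 and 300 exchanged).

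The 24 h biofilm and stationary cells differed in 903 tags, 276 higher and 627 lower in the biofilm as labelled (627 and 276 exchanged). Of these, 229 higher and 574 lower as labelled (574 and 229 exchanged) differed at least 2-fold. The 2 RNA samples of the 24 h biofilm, less each tag's mean sample difference, were that far apart for 595 tags. BCE4512 (67.6-fold, log2 −6.08 ± 0.54, adjusted p = 0.0054) and BCE5405 (54.9-fold, log2 −5.78 ± 0.79, adjusted p = 0.012) were higher in stationary cells as labelled and in the biofilm exchanged. BCE1517 (23.6-fold, log2 4.56 ± 0.94, adjusted p = 0.034) and BCE5032 (22.3-fold, log2 4.48 ± 0.31, adjusted p = 0.0054) were higher in the biofilm as labelled and in stationary cells exchanged. The 4 folds were 61.8, 52.3, 22.6 and 21.6 under median centring, and the median signals after the exchange differed 84.1-, 48.3-, 19.0- and 19.6-fold. The 20 tested tags from 114 to 133 had a median log2 of 2.69 (−2.69 exchanged; permutation p = 0.001). The 7 from 1331 to 1337 had one of −3.51 (3.51 exchanged; permutation p = 0.003). The plasmid list did not pass camera's test (adjusted p = 0.298, and 0.748 with the estimated correlation). It had 1 tag higher as labelled, 6 lower (6 and 1 exchanged) and, in limma's test, 0 adjusted over the list alone. Its median log2 of 0.06 and mean of −0.10 differed in sign, and the median was −0.03 under scale normalization, 0.36 with processed signals and 0.13 at an offset of 10 (−0.06, 0.10, 0.03, −0.36 and −0.13 exchanged). Without stationary sample 1 limma called 0 tags, with 1023 at an unadjusted p under 0.05, and the count was 161 without stationary sample 2, 449 without mid-log sample 2, 524 without 12 h biofilm sample 1 and 541 without mid-log sample 1, while BCE1517 was also not called without any of mid-log samples 1 and 2, stationary sample 2, 12 h biofilm sample 2 and 24 h biofilm sample 1 (adjusted p = 0.0508 to 0.127), BCE5032 without stationary sample 2 (adjusted p = 0.0549) and BCE5405 without 24 h biofilm sample 2 (adjusted p = 0.077). Other settings gave 231 to 3218 tags, BCE1517 was not called without the array of stationary sample 1 with 12 h biofilm sample 2 (adjusted p = 0.0558), without that of mid-log sample 1 with stationary sample 2 (adjusted p = 0.0743) or with weights by condition (adjusted p = 0.0535), and the split as labelled was 989 higher and 1020 lower with the processed signals, 1007 and 1046 in the authors' value table and 146 and 653 with separate channels (1020 and 989, 1046 and 1007, and 750 and 489 exchanged).

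Between the 2 biofilm ages, 1005 tags differed, 386 higher and 619 lower at 24 h as labelled (619 and 386 exchanged). Of these, 293 higher and 528 lower as labelled (528 and 293 exchanged) differed at least 2-fold. The 2 RNA samples of the 24 h biofilm, less each tag's mean sample difference, were that far apart for 595 tags. BCE2555 (fitted fold 348, log2 −8.44 ± 1.20, adjusted p = 0.013) and BCE2346 (200-fold, log2 −7.64 ± 0.19, adjusted p = 0.00076) were higher at 12 h as labelled and at 24 h exchanged. BCE1055 (62.6-fold, log2 5.97 ± 0.71, adjusted p = 0.0085) and BCE1976 (58.2-fold, log2 5.86 ± 0.70, adjusted p = 0.0087) were higher at 24 h as labelled and at 12 h exchanged. The 4 folds were 69.1, 111, 59.7 and 62.2 under median centring, and the median signals after the exchange differed 42.5-, 81.0-, 104- and 83.6-fold. For BCE2555 the fitted fold was above any ratio of its signals, at most 302, and it had values on 8 of 12 arrays and BCE2346 on 9. After the exchange, BCE1055 read 6731 to 12651 scanner units in the 12 h biofilm and at most 242 in the other 3 conditions. The 7 tested tags from 322 to 328 had a median log2 of 3.45 (−3.45 exchanged; permutation p = 0.001), and the 7 from 2948 to 2954 one of −1.73 (1.73 exchanged; permutation p = 0.002). All 7 tags of the first run were also called between the 12 h biofilm and stationary cells, with a median log2 of −3.42 (3.42 exchanged), and 0 between the 24 h biofilm and stationary cells. On the plasmid, 4 tags were higher as labelled and 21 lower (21 and 4 exchanged), or 3 and 12 adjusted over the list alone. The list's camera adjusted p of 0.0316 rose to 0.582 with the estimated correlation, 0.585 with separate channels as labelled (but 0.0215 exchanged), 0.145 without a filter on dim probes, 0.111 with that filter exchanged, 0.283 without 24 h biofilm sample 2, 0.264 without 12 h biofilm sample 2 and 0.0935 without stationary sample 2. Counts were 160 without 12 h biofilm sample 2, 175 without 12 h biofilm sample 1, 346 without stationary sample 1, 415 without mid-log sample 2, 451 without stationary sample 2, 534 without mid-log sample 1, 576 without 24 h biofilm sample 1 and 660 without the array of stationary sample 1 with 24 h biofilm sample 2, and BCE1055 and BCE1976 were not called without stationary sample 1 (adjusted p = 0.0547 and 0.0596) or 12 h biofilm sample 2 (adjusted p = 0.0566 and 0.053). Other settings gave 255 to 3251 tags, and the split as labelled was 806 higher and 796 lower with the processed signals, 825 and 814 in the authors' value table, 672 and 447 under median centring and 94 and 524 with separate channels (796 and 806, 814 and 825, 447 and 672, and 706 and 660 exchanged).

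The change over time was then compared between growth modes, as the change from 12 to 24 h in biofilm minus the change from mid-log to stationary phase. The labels give hours for the biofilms only. The 2 changes may thus span unlike intervals, and a difference need not come from the growth mode. The change differed for 856 tags, 472 with a higher and 384 with a lower value in biofilm as labelled (384 and 472 exchanged). Of these, 468 higher and 381 lower as labelled (381 and 468 exchanged) differed at least 2-fold. The 2 RNA samples of the 24 h biofilm, less each tag's mean sample difference, were that far apart for 595 tags. BCE1392 had a difference of 11.63 log2 (± 1.86, adjusted p = 0.022) and BCE2376 of 9.49 (± 1.48, adjusted p = 0.021) as labelled, and −11.63 and −9.49 exchanged. BCE0166 had −6.19 (± 0.71, adjusted p = 0.015) and BCE4238 −5.66 (± 1.20, adjusted p = 0.038) as labelled, and 6.19 and 5.66 exchanged. Under median centring the 4 values were 8.65, 7.67, −7.95 and −6.88 as labelled, and −8.65, −7.67, 7.95 and 6.88 exchanged. The 17 tested tags from 1517 to 1533 had a median of 3.69, and 6.37 with processed signals (−3.69 and −6.37 exchanged). The 12 from 1766 to 1777 had one of −2.94, and −5.13 with processed signals (2.94 and 5.13 exchanged; permutation p = 0.001 for each run). All 17 tags of the first run were called between stationary and mid-log cells, lower in stationary cells as labelled and higher exchanged, and 5 between the 2 biofilms, where the median log2 was 0.69 (−0.69 exchanged). On the plasmid, 4 tags had higher values as labelled and 40 lower (40 and 4 exchanged), or 6 and 50 adjusted over the list alone. The median was −0.47, and −0.72 at an offset of 10 (0.47 and 0.72 exchanged), and it also grew by over 1.5 times with processed signals. It stood against −0.07 for the other tags (0.07 exchanged). The camera adjusted p was 2.04e-05, and the adjusted p 0.503 with the estimated correlation. Limma called 0 tags without 12 h biofilm sample 2, mid-log sample 1 or 2, or stationary sample 1 or 2 (1009 to 1433 at an unadjusted p under 0.05), 427 without 12 h biofilm sample 1, where BCE1392 was not called (adjusted p = 0.052), and 514 without the array of stationary sample 1 with 24 h biofilm sample 2, without BCE1392 and BCE4238 (adjusted p = 0.0501 and 0.0633), and BCE4238 was also not called without 24 h biofilm sample 2 (adjusted p = 0.0674) or the array of 24 h biofilm sample 1 with mid-log sample 2 (adjusted p = 0.0557). Other settings gave 0 tags at an adjusted p threshold of 0.01 (1767 at an unadjusted p under 0.05) to 2962. The majority turned under scale normalization, with 457 higher and 466 lower as labelled (466 and 457 exchanged). It also turned with the 12 arrays as units, with 1353 and 1609 (1609 and 1353 exchanged), and without 24 h biofilm sample 1. Separate channels gave 206 higher and 41 lower as labelled, without BCE0166 (adjusted p = 0.348), and 583 and 666 exchanged, with it. The brightest probe gave no call for BCE0166 and BCE4238 (adjusted p = 0.055 and 0.0886).

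Some tags set one condition or growth mode apart from all others. Both biofilms differed from both planktonic phases, called the same way in all 4 pairs, for 348 tags, 119 higher and 229 lower in biofilm as labelled (229 and 119 exchanged). Mid-log cells differed from each of the other 3 conditions for 345 tags higher and 396 lower as labelled, the 24 h biofilm for 11 and 321, the 12 h biofilm for 21 and 232, and stationary cells for 7 and 47 (396 and 345, 321 and 11, 232 and 21, and 47 and 7 exchanged). Plasmid tags made up 47 of the 396 tags lower in mid-log cells as labelled (higher exchanged) and 2 of the 345 higher. The comparisons share RNA samples. In 100 simulations without change the mean number was 0 for each set, but without change limma has almost no tags to call. This 0 therefore does not show what the shared RNA samples add to an overlap. Independent lists would share 0.978 higher and 4.19 lower tags for biofilm against planktonic and 41.9 and 17.3 for mid-log cells as labelled. For stationary cells they would share 6.31 higher and 3.56 lower, so the 7 tags higher as labelled were near that number. The values were 11.3 and 9.63 for the 12 h biofilm and 3.78 and 19.0 for the 24 h biofilm. Part of the excess may come from the shared samples. The 348 tags numbered 0 without stationary sample 1, where limma called 0, 2, 1395 and 1822 tags in the 4 pairs,, 54 without stationary sample 2, 121 without 12 h biofilm sample 2, 149 without mid-log sample 2, 161 without 12 h biofilm sample 1, 162 without mid-log sample 1 and 217 without 24 h biofilm sample 2. They numbered 52 at an adjusted p threshold of 0.01, 165 with the filter asking for all 24 channels, 176 with the brightest probe, 186 with separate channels as labelled (501 exchanged), 632 at an offset of 10, 876 with processed signals, 892 in the authors' values and 1262 with the 12 arrays as units.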

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

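Chosen after the result was seen were the test of plasmid copy number and the reading of the stretch test by its upper limit. The tests on probe composition and on stretches of tags were set before.

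The biofilm change from 12 to 24 h differed from the mid-log to stationary change for 856 tags in limma's test of the difference itself. It was higher in biofilm for 472 as labelled and lower for 384 (384 and 472 exchanged). The planktonic phases carry no hours, so growth mode need not be the only difference between these changes. For BCE1392 (11.63 as labelled, −11.63 exchanged), the change as labelled was 3.87 ± 1.32 log2 in biofilm (adjusted p = 0.1) and −7.76 ± 1.32 in planktonic cells (adjusted p = 0.017; −3.87 and 7.76 exchanged). For BCE2376 (9.49 as labelled, −9.49 exchanged), it was 2.81 ± 1.05 (adjusted p = 0.12) and −6.67 ± 1.05 (adjusted p = 0.014; −2.81 and 6.67 exchanged). BCE0166 (−6.19 as labelled, 6.19 exchanged) changed by −0.90 ± 0.50 in biofilm (adjusted p = 0.26) and 5.29 ± 0.50 in planktonic cells (adjusted p = 0.004; 0.90 and −5.29 exchanged). BCE4238 (−5.66 as labelled, 5.66 exchanged) changed by −4.07 ± 0.85 (adjusted p = 0.034) and 1.59 ± 0.85 (adjusted p = 0.23; 4.07 and −1.59 exchanged). Under median centring the 4 differences were 8.65, 7.67, −7.95 and −6.88 as labelled and −8.65, −7.67, 7.95 and 6.88 exchanged. In the first 3 tags the planktonic part was the larger one. Without any of mid-log samples 1 and 2, stationary samples 1 and 2 and 12 h biofilm sample 2, limma called 0 tags (1352, 1368, 1009, 1200 and 1433 at an unadjusted p under 0.05), none of the 4 named ones among them. BCE1392 was also not called without 12 h biofilm sample 1 (adjusted p = 0.052) nor BCE4238 without 24 h biofilm sample 2 (adjusted p = 0.0674), and the count was 427 without 12 h biofilm sample 1.

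For the plasmid list, the biofilm change minus the planktonic one had a mean of −0.69 log2 as labelled and 0.69 exchanged. Its camera adjusted p was 2.04e-05 at the preset correlation, which did not hold with an estimated one (adjusted p = 0.503). None of 10000 chromosomal lists matched for GC content and brightness had a mean as far out (0%, range −0.42 to 0.21), which argues against probe composition as the cause. Copy number alone would move the plasmid tags together, but 47.7% of them lay within 2 SE of the list's median, against 59.4% of chromosomal tags around theirs. The shares were 63.5 against 52.7% between the biofilms and 40.6 against 52.5% between stationary and mid-log cells. As these parts of the difference go opposite ways, copy number was not settled. Neighbouring tags that vary together by chance also stay open, as does a biological difference in plasmid expression, since 3.23% of stretches of as many consecutive chromosomal tags had a mean as far out. The 3.23% alone would have counted against chance, and the rule was changed after it was seen to one on its upper limit of 17.0%, because the stretches overlap and only 26 are separate.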

How the results depend on the processing

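Chosen after the data were examined were the exchanged detection filter, exchanged separate channels, weights by condition, leaving out the 24 h biofilm arrays or the probes apart in 1 sample, the sRNA list and the windows. No value of a named tag and no called result of the plasmid list turned sign in an alternative, and signs of other called tags were compared only with exchanged separate channels. Of the values recomputed, 105 counts moved by more than 1.5 times, 85 results no longer passed a threshold and 1560 stayed within these limits. Unless a reason is given, the cause was not tested. Comparisons come in the order 24 h against 12 h biofilm, 12 h biofilm against stationary, 24 h biofilm against stationary, 12 h and then 24 h biofilm against mid-log, stationary against mid-log, biofilm against planktonic, and the change over time.

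With the 12 arrays as units, which ignores that RNA samples recur, limma called 3251, 3420, 3218, 3689, 4200, 3266, 3964 and 2962 tags. At an adjusted p threshold of 0.01, a stricter limit, it called 255, 306, 231, 1066, 1413, 364, 1227 and 0 (1767 at an unadjusted p under 0.05). The filter asking for all 24 channels left 3454 tags to test and called 412, 597, 399, 1177, 1363, 749, 1204 and 387. Processed signals gave 1602, 2199 and 2009 in the first 3 comparisons, 2263 for stationary against mid-log and 1496 for the change over time, and the authors' values gave 1639, 2249, 2053, 2299 and 1530. Separate channels as labelled called 618, 583, 878, 691, 1338 and 247 tags, without 24 h biofilm against stationary and mid-log, which stayed within the range. That fit assigns each channel to its labelled RNA sample. The correlations between channels of the same RNA sample argue against this assignment (mean r −0.32 as labelled, 0.93 exchanged). Exchanged separate channels called 1366, 1582, 1239, 2598, 2847, 1633, 2767 and 1249, with 954, 1121, 864, 2158, 2430, 1138, 2368 and 824 of the reported calls among them and 0 in the opposite direction. The brightest probe gave 597, 672, 538 and, for the change over time, 470. An offset of 10 gave 1567 for 24 h biofilm against stationary. Without the 24 h biofilm arrays, which leaves 6 arrays, 691 tags were called for 12 h biofilm against stationary and 623 for stationary against mid-log.

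Leaving out 1 RNA sample leaves its condition with a lone sample, assumed to vary like the others, on 2 residual degrees of freedom. The counts then ran over 160 to 867, 2 to 1223, 0 to 824 (unadjusted 1023), 1066 to 2187, 1361 to 2253, 2 to 1134, 1083 to 2082 and 0 to 692. The lowest came without 12 h biofilm sample 2, stationary sample 1 (2nd and 3rd), mid-log sample 1, mid-log sample 2, stationary sample 1 (6th and 7th) and, at 0, any of mid-log samples 1 and 2, stationary samples 1 and 2 and 12 h biofilm sample 2 (unadjusted 1009 to 1433). Leaving out 1 array gave 660 to 1097, 814 to 1331, 709 to 1041, 1839 to 2402, 2235 to 2720, 806 to 1475, 2092 to 2541 and 514 to 1038, where 660 and 514 came without the array of stationary sample 1 with 24 h biofilm sample 2.

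Without the block of RNA sample number (the dye), the counts were 1166, 1376, 1088, 2354, 2671, 1410, 2576 and 1062, all within 1.5 times the reported ones. A slide block was not run, since each slide held 1 array.

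The plasmid list's adjusted p, 0.0316 between the biofilms and 0.00375 for 12 h biofilm against stationary, was 0.585 and 0.181 with separate channels as labelled and 0.0215 and 0.00361 exchanged. Between the biofilms it was 0.145 without a filter and 0.111 with the exchanged filter, and 0.00273 to 0.283 over the leave-outs, past the threshold except without stationary sample 2 (0.0935), 12 h biofilm sample 2 (0.264) and 24 h biofilm sample 2 (0.283). An estimated correlation gave 0.582, 0.514 and, in the last 5 comparisons, 0.503. Over the leave-outs the others ran over 0.00105 to 0.0386, 0.148 to 0.696, 6.68e-07 to 6.12e-06, 0.000218 to 0.00176, 4.51e-05 to 0.00103, 1.28e-05 to 7.92e-05 and 2.75e-06 to 0.000559.

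Of 1235 recomputed values, from 32 pairs of a named tag and a comparison, 1164 kept their call and 71 lost it, 6 of them with separate channels as labelled. The plasmid list's medians moved by over 1.5 times in 8 of 8 comparisons with processed signals and at an offset of 10, for biofilm against planktonic from 0.29 to 0.96 and 0.55 as labelled (−0.29, −0.96 and −0.55 exchanged). Median centring moved the median of all tags by −0.12 (12 h biofilm against stationary) to 0.18 (24 h biofilm against mid-log) as labelled, and the processed signals and authors' table by up to 0.17.

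Signal over background limited dim tags, with 58.5 to 92.1% of spots well above background in a channel.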

Other observations

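Chosen after the result was seen were the sRNA list, the windows, and the tests on the channels, on the probes apart in 1 sample and on splits.

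The 77 sRNA tags leaned one way against mid-log cells. As labelled, 7 were higher and 38 lower in the 24 h biofilm (38 and 7 exchanged; median −0.94 as labelled, 0.94 exchanged), 7 and 30 in the 12 h biofilm (30 and 7 exchanged) and 3 and 21 in stationary cells (21 and 3 exchanged). The camera adjusted p values were 0.00439, 0.00908 and 0.00908, also 0.00908 for biofilm against planktonic cells, and 0.0653 to 0.543 in the other 4 comparisons. With an estimated correlation of 0.177, the adjusted p was 0.755 to 0.845 throughout. Their median turned sign under median centring between the biofilms and between the 12 h biofilm and stationary cells. Against mid-log cells it shrank under that setting from −0.94 to −0.24 in the 24 h biofilm, from −0.53 to −0.45 in the 12 h biofilm and from −0.46 to −0.09 in stationary cells (0.24, 0.45 and 0.09 exchanged).

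Among 57 windows of 100 tag numbers, tags 101 to 200 had 54 higher and 10 lower of 97 in biofilm as labelled (10 and 54 exchanged; median 1.36 as labelled, −1.36 exchanged; camera adjusted p = 6.03e-07). In the change over time, tags 1501 to 1600 had 36 higher and 1 lower of 94 (1 and 36 exchanged; adjusted p = 2.88e-06). From 1 to 9 windows passed per comparison, and 0 with an estimated correlation (camera, lowest adjusted p = 0.75). Log2 values of neighbouring tags correlated at 0.378 to 0.488 across tags, which are not independent replicates, and at −0.029 to 0.028 at a distance of 50.

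For biofilm against planktonic cells, splits of the 8 RNA samples were counted. Without the RNA sample number, limma called 864 tags in the real split and at most 190 in any other of the 35, so 1 split gave as many. With that number as a term, it was 648 against at most 105. Only 3 of the splits, the real one included, keep both RNA samples of each condition together, and the other 32 part a condition, which leaves too few like splits for a share under 0.05.

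As labelled, single-channel levels of 1 RNA sample did not correlate across its 3 arrays. Turning 1 array alone raised the residual SD from 0.353 to between 0.719 and 1.12, which argues against an error on some arrays only. Brightness or normalization would have lowered the correlations in either reading, but after the exchange the lowest was 0.772 and the mean 0.932. This fits an exchange of the channels on every array, or of the 2 arrays of every dye-swapped pair, which cannot be separated since dye and RNA sample number coincide. Under either, the exchanged directions would hold, and the correlations argue against the labelled ones. No record of the hybridisations was available to check this.

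In 24 h biofilm sample 1, 324 probes were at least 3 log2 lower as labelled and 8 higher (324 higher and 8 lower exchanged), against at most 56 in any other RNA sample. Of 306 tags with several measured probes, 6 (1.96%) moved in more than 1, which argues against a change of the transcripts. All 285 probes measured on its 3 arrays deviated on each (100%), so their deviation did not rest on 1 array. The probes were chosen by a level fitted over these 3 arrays, which favours such probes. A defect of 1 array in other probes was therefore not tested. Carrying any of 20 words of 8 bases, chosen on part of the probes, was commoner in the held-out ones (56 of 162 against 179 of 7922; odds ratio 22.8, Fisher's exact p = 1.2e-46, two-sided), so labelled molecules that bind through short shared sequences may be a cause. Without these probes the counts were 1116, 1311, 1036, 2323, 2649, 1372, 2583 and 954, in the order of the comparisons above.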
